A study of Drosophila melanogaster with 2 samples.

How the data were processed

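The series compared RNA from Drosophila melanogaster of 2 genotypes, the control yw, which carries the body colour mutation yellow and the eye colour mutation white, and homozygous mbf1 mutants. Per the labels, the animals were embryos kept for 16 h after egg laying at 25 °C. Total RNA of each genotype was labelled with biotin and hybridised to 1 Affymetrix array of the first Drosophila genome chip, so each group had 1 array and there were 2 arrays in all.

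The deposited values are intensities on a linear scale, 1 per probe set and array. MAS5, which computes 1 signal per probe set from its matched and mismatched probes, is named per the submitters' processing notes. Its version and target level are not given in the sources used here. The deposited intensities had not been brought to a common level: the mean after trimming 2% at each end was 60.1 on the yw array and 87.8 on the mbf1 array. Detection calls were not used here, and neither were the scanner and fluidics settings of the arrays. The value table held 0 columns beyond the 2 arrays.

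The table held 14010 probe sets, of which 44 were controls. GEO's platform annotation gave 1 gene symbol for 12443 probe sets, several for 327 and none for 1240. Symbols were brought up to date by gene identifier for 12393 probe sets through a gene table of the Release 6 assembly, which changed 0 of them, and the others kept the symbol of the annotation. No genome build is named in the sources used here, so no coordinates are given, and the gene table served only for names and for which genes neighbour each other. A gene with several probe sets, which was the case for 1209 of 10843 genes, was represented by the one with the highest mean signal.

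The log2 ratio of the mbf1 array over the yw array was centred on its median over probe sets brighter than the median of their own array on both arrays. This removed a difference of 0.55 on the log2 scale, or 1.47-fold. A floor was then set at the 40th percentile of both arrays' scaled values pooled, a signal of 17.7, and values under it were raised to it. A fold from or to the floor is a lower bound and is written as at least N-fold. A gene was called measured when it was above the floor on at least 1 array, and it was counted as higher or lower when its log2 ratio was at least 1 in size. Signals given in the text are after scaling.

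With 1 array per genotype no test between genotypes was possible, and no p-values were computed. The disagreement between probe sets of 1 gene, which leaves out error between arrays, was described from genes with at least 2 probe sets above the floor on both arrays. Gene lists were described by the median log2 ratio of their measured members and by the percentile of that median among 10000 random lists of the same size, matched on deciles of mean signal. A list of at least 5 measured genes was said to stand apart when its median lay under the 2.5th or over the 97.5th percentile, which describes these 2 arrays and not the genotypes. The 39 lists, the scaling, the floor, the threshold and the alternatives were fixed before the data were examined, with the exceptions named here. Lists of seminal fluid, phototransduction and yolk proteins, a shorter list of cytochrome P450 genes, and scaling on hybridization controls were added after seeing the data.

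Genes were named by a rule fixed before the data were examined: mbf1, the 15 largest and the 15 smallest log2 ratios, up to 4 members of each list with the largest ratios in size, all members at least 2-fold apart in lists that stood apart, all Hox genes and E(z). Genes named outside this rule are said to have been chosen after their values were seen.

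Alternatives were the values as deposited, quantile normalization, loess with a span of 0.3, a floor at the 25th or the 60th percentile, a pseudocount at the 10th percentile of pooled values in place of the floor, genes above the floor on both arrays, the mean over a gene's probe sets, probe sets without a suffix for shared sequence, and a threshold of 1.5-fold or 3-fold. A result without replicates counted as moved when a ratio differed from its main value by more than the robust SD of ratios among the 500 genes of nearest signal, or a list median by more than the SD of its random lists.

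The procedure was tested on simulated data made from the yw array, with 200 genes changed, a bulk difference of 0.5 and noise of 0.37 (SD, log2). Translation factor genes not among the 200 were also shifted by -0.4. The procedure recovered 92.2% of 102 genes changed by 1.5 on the log2 scale and 98.0% of 98 genes changed by 2.5, and it counted 0.375% of 7197 unchanged genes. The shifted list, with 39 measured genes, lay below all its random lists. The 200 genes were drawn from genes well above the floor on the yw array, and the noise had the same SD at all signals. These shares therefore do not describe genes near the floor. Of 1000 lists drawn at random from the unchanged genes, 3.8% stood apart. The simulated noise was independent between genes, so this rate does not describe lists whose genes vary together. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.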

Results

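Transcript levels of yw and homozygous mbf1 mutant Drosophila, both labelled as embryos, were measured on 1 Affymetrix array per genotype. The comparison addressed which genes depend on MBF1, multiprotein bridging factor 1, a coactivator that links transcription factors to the TATA-binding protein. Of 10843 genes with a named probe set, 7145 were above the floor on the yw array and 7183 on the mbf1 array. On at least 1 array 7675 genes, or 70.8%, were above the floor, and 6653 were above it on both. There were no replicates, so no value below carries a replicate error, and each difference is one between these 2 arrays.

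The mbf1 transcript itself gave the lowest ratio among the genes above the floor on both arrays. Its signal was 478.7 on the yw array and 22.1 on the mbf1 array, a log2 ratio of -4.44 or 21.7-fold lower, and the second value lay close to the floor of 17.7. The gene was read by 1 probe set, and the labels do not say which part of the gene the mutation removes.

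Genes known from adult male tissues were bright on both arrays, although both are labelled as embryos. The testis list had a median signal of 226 on the yw array and 225 on the mbf1 array, with 25 and 27 of its 33 genes above the floor; without alphaTub84D, twe, Mst57Da and Mst57Dc, which are not particular to the testis and were picked out after their values were seen, the median of the genes' mean signals was 94.3 instead of 225. Its member Mst77F, a sperm chromatin protein, had signals of 258.7 and 425.2. Several lists of genes active in embryonic development were dim. The early zygotic genes had median signals of 13.6 and 11.7, neuroblast genes 14.7 and 9.94, and cell cycle genes 12 and 11.6, all under the floor. Salivary gland genes were under it too, at 8.63 and 7.94. Neuron genes, at 17.8 and 21.0, and tracheal genes, at 19.0 and 22.5, lay slightly above it. No array here gives the level to expect of these lists in embryos of 16 h, so their dimness does not speak against the labels. The Hox genes with a named probe set, pb, Dfd, Scr and Antp, were under the floor on both arrays, so no ratio is given for them. Signals of different probe sets are not on one scale, so these levels describe brightness and not transcript number.

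**Figure D1:**
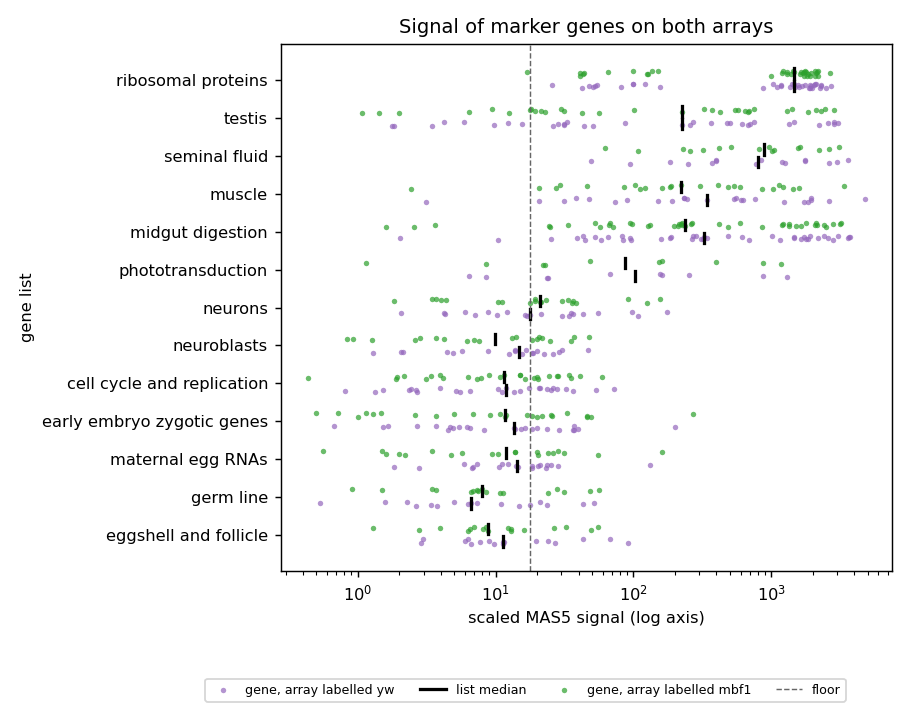
Scaled MAS5 signal on a log axis for the genes of 13 lists, with 1 point per gene and array (purple, yw; green, mbf1), black bars for list medians and a dashed line for the floor at 17.7. Medians of the testis list lie at 226 and 225 (median mean signal 94.3 without 4 genes not particular to the testis), while those of neuroblast, cell cycle and early zygotic genes lie under the floor; the seminal fluid and phototransduction lists were added after seeing the data.

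Most genes differed little between the arrays. Relative to the bulk of genes, 84.8% of the measured genes differed by less than 1.5-fold, and across genes, which are not independent replicates, the log2 signals of the arrays correlated with a Pearson r of 0.92 and a Spearman rho of 0.92. At least 2-fold higher on the mbf1 array were 116 genes, and 124 were at least 2-fold lower, together 3.13%. Of these, 33 of the higher genes were under the floor on the yw array and 32 of the lower ones under it on the mbf1 array. Ratios reached at least 4-fold for 11 higher and 14 lower genes. Without scaling between the arrays the numbers were 797 higher and 34 lower, and with scaling on hybridization controls they were 235 and 77. In 260 genes with several probe sets above the floor, the SD of a single log2 ratio estimated from the disagreement of 2 probe sets was 0.38, and 5% of the pairs disagreed by more than 1.03. A disagreement of a pair holds the error of 2 ratios, so 1.03 is not a limit for 1 ratio. The pairs also come from the same 2 arrays, so the SD leaves out error between arrays or samples. A 2-fold difference read by 1 probe set therefore cannot be judged by it alone.

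**Figure D2:**
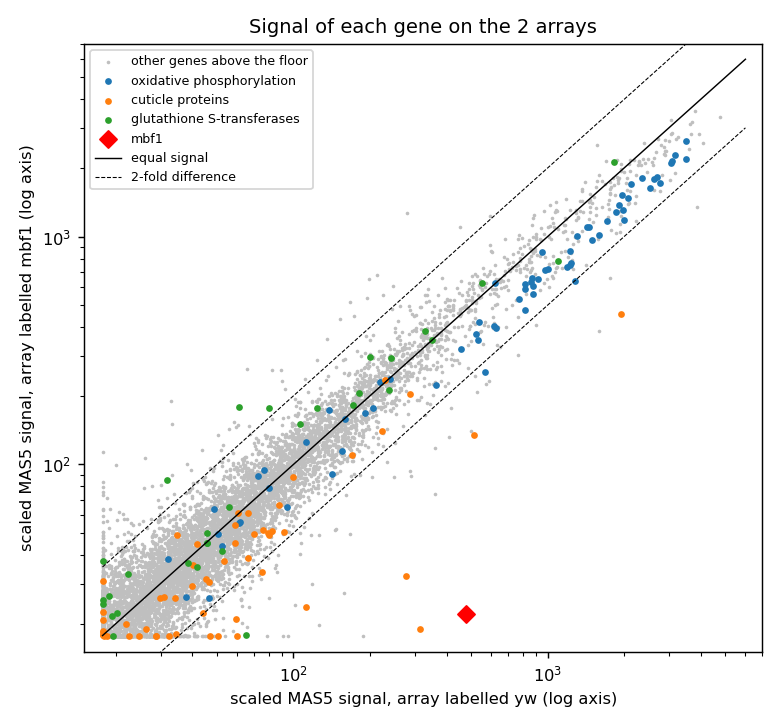
Scaled MAS5 signal of each measured gene on the mbf1 array against the yw array, both on log axes, with values under the floor drawn at the floor of 17.7. Solid and dashed lines mark equal signal and a 2-fold difference; mbf1 (red) lies at 478.7 and 22.1, and 62 of the 70 oxidative phosphorylation genes (blue) lie below the line of equal signal, with a median log2 ratio of -0.48 (0.073 without scaling between the arrays).

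Cuticle genes were 4 of the 14 genes at least 4-fold lower and 10 of the 124 at least 2-fold lower. Acp65Aa, an adult cuticle protein, had signals of 314.7 and 19.0, a log2 ratio of -4.05, and Cpr92F had a ratio of -3.11. Acp1, also an adult cuticle protein and much brighter, had signals of 1946 and 459, or 4.24-fold lower, and Cpr100A was 4.76-fold lower. The list of 55 measured cuticle proteins, which holds genes of larvae and adults, had a median log2 ratio of -0.49, lower than in all 10000 random lists (0.052 without scaling and -0.29 with scaling on hybridization controls, where the median of all genes was 0.50 and 0.19). In it 44 ratios were negative and 0 genes were at least 2-fold higher. The other 6 of the 10 genes at least 2-fold lower were Cpr49Ae at -1.93, Cpr47Ea, Cpr62Bc, Cpr76Bd, Cpr97Eb at -1.16 and obst-B at -1.51, with Cpr47Ea at least 3.38-fold, Cpr62Bc at least 2.85-fold and Cpr76Bd at least 2.65-fold lower. Genes of chitin and cuticle maturation had a median of -0.19 at the 1.47th percentile, with the chitin deacetylase gene serp at -1.11, though its other probe set gave -0.29. That list lost its place outside the random lists in 7 of 10 alternatives and had a median of 0.35 without scaling and 0.033 with scaling on hybridization controls.

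Respiratory chain and muscle genes were lower as groups, by less than 2-fold for most members. Of 70 oxidative phosphorylation genes, 62 had negative ratios and 2 were at least 2-fold lower, the complex I gene ND-15 at -1.15 and RFeSP, the Rieske protein of complex III, with signals of 1282 and 639.9. The median was -0.48, lower than in all random lists (0.073 without scaling and -0.26 with scaling on hybridization controls). Glycolysis genes had a median of -0.34 at the 1.91th percentile (0.22 without scaling and -0.12 on hybridization controls), with Pglym78 at -0.87 and Pfk at -0.66. This list no longer stood apart after quantile normalization, at -0.16, or loess, at -0.25. Muscle genes had a median of -0.38 at the 0.02th percentile (0.17 without scaling and -0.17 on hybridization controls), with 21 of 24 ratios negative. The flight muscle genes fln and Act88F had ratios of -1.34 and -0.84, and the muscle LIM protein gene Mlp60A one of -1.18. Ribosomal proteins, also a bright list, had a median of -0.02 at the 49.7th percentile, and quantile normalization moved that list above its random lists.

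Digestive genes were lower and tubule genes higher. The midgut digestion list had a median of -0.32, below all random lists (0.23 without scaling and -0.11 with scaling on hybridization controls), and 35 of its 41 ratios were negative. The lysozyme genes parted, with LysP at least 5.37-fold lower and LysX 4.01-fold higher, and the maltase gene Mal-A3 was 3.05-fold lower. Malpighian tubule genes had a median of 0.28 at the 98.0th percentile, with mal, which sulfurates molybdenum cofactor enzymes, at 1.20 and salt at 0.83. This list lay within its random lists under 3 of 10 alternatives, and its median was 0.83 without scaling and 0.49 with scaling on hybridization controls. Eggshell genes had a median of -0.42 at the 0.92th percentile (-0.0077 without scaling and -0.26 with scaling on hybridization controls), but only 6 were measured, and the brightest of those named, Cp18, had signals of 91.0 and 49.3.

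Glutathione S-transferases, aminoacyl-tRNA synthetases, translation factors and heat shock proteins were higher as lists, relative to the bulk of genes. Without scaling between the arrays their medians were 0.73, 0.83, 0.70 and 0.80, and with scaling on hybridization controls 0.40, 0.51, 0.37 and 0.47, where the median of all genes was 0.50 and 0.19. After centring on the bulk, glutathione S-transferases had a median of 0.18 at the 98.95th percentile, with 4 of 31 at least 2-fold higher. These were GstD9 at 1.54, GstD5 at 1.43, GstD2 at 1.15 and GstD10, at least 2.12-fold higher, all of the delta class, while GstE4 was 3.64-fold lower. Aminoacyl-tRNA synthetases had a median of 0.30 at the 99.5th percentile, with GluProRS 2.04-fold and AlaRS at least 2.26-fold higher, and both were dim on the yw array. Translation factors had a median of 0.14 at the 98.9th percentile, with eIF6 at 0.99 and eIF4G1 at 0.85, against eRF3, a termination factor, at -1.01. Quantile normalization put that list at the 97.3th percentile. Heat shock proteins had a median of 0.25 at the 98.9th percentile, with Hsc70-2 at 0.48 as the largest ratio among its 15 genes with a probe set of their own, and a floor at the 60th percentile put that list at the 97.1th. Probe sets annotated with several genes, some of them heat shock genes, were not used for it.

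Immune effector genes had a median of 0.20 at the 99.4th percentile (0.71 without scaling and 0.42 with scaling on hybridization controls), with members on both sides. Mtk, the antifungal peptide metchnikowin, had the highest ratio among the genes above the floor on both arrays, with signals of 33.1 and 190.1, or 5.74-fold higher. PGRP-SC2, a peptidoglycan amidase, was 3.10-fold higher, Listericin 2.91-fold and the attacin gene AttD 2.02-fold. Def, the antibacterial peptide defensin, was at least 5.12-fold lower, and BomBc2, a bomanin, was 2.54-fold lower. Among hemocyte genes, whose median was 0.07, the prophenoloxidase genes PPO1 and PPO2 were 2.47-fold and 2.33-fold higher.

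Among the remaining genes with the largest ratios, CG11893 was at least 6.39-fold higher, CG9344 4.93-fold and CG10725 at least 4.73-fold. CG10912 was the brightest of them, with signals of 280.4 and 1268, and CG12868 was 4.51-fold higher. The splicing factor gene Phf5a, the nucleotidase gene NT5E-2 and CG13155 were at least 4.49-fold, 4.26-fold and 4.13-fold higher. The UDP-glucose dehydrogenase gene sgl was 4.08-fold higher, and CG10958 was 3.86-fold higher. CG13605, Cyp6a17 and CG13794 were at least 3.60-fold, 3.56-fold and 3.36-fold higher. Of the remaining lowest ratios, CG9953 was at least 10.6-fold lower, CG4375 6.40-fold, CG8736 4.87-fold and Vajk3 at least 4.44-fold. Cyp6a9 was 5.81-fold and CG7214 4.12-fold lower, with CG7214 at signals of 1589 and 385.5. The folate enzyme gene Nmdmc was 3.97-fold lower. The homeobox gene tup was 4.22-fold lower, but its other probe set was under the floor. The P450 genes went both ways, with Cyp6a23 3.40-fold lower and Cyp4p1 3.36-fold higher, and their list median was -0.01.

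Medians of the chromatin and signalling lists lay within their random lists in the main setting. Several of these lists were small and dim, so that range was wide. For the 9 measured of 19 Polycomb group genes it ran from -0.35 to 0.34, and for 7 of 26 ecdysone genes from -0.32 to 0.34. A shift within such a range would not be seen. Polycomb group genes had a median of -0.01 and trithorax group genes one of 0.02, and the Polycomb gene E(z) had a ratio of 0.13 at signals of 21.2 and 23.1, close to the floor. With a floor at the 25th percentile the trithorax list lay above its random lists. Other Polycomb targets had a median of 0.13 over 12 measured genes, and JNK and AP-1 signalling genes one of 0.05. Antioxidant enzymes had a median of -0.04, with the mitochondrial superoxide dismutase gene Sod2 at -0.77. The amino acid and ATF4 response list had a median of 0.00, mRNA decay genes 0.08, cell cycle genes -0.03 and ecdysone genes 0.16.

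Other marker lists also lay within their random lists. Medians were -0.16 for tracheal genes, 0.13 for neurons, -0.05 for glia, 0.01 for neuroblasts, -0.08 for fat body and -0.18 for salivary gland. The tracheal list lay under its random lists with a floor at the 60th percentile and over genes above the floor on both arrays. In the fat body list, the larval storage protein gene Lsp2 was 2.53-fold lower. Medians were 0.29 for germ line, 0.22 for maternal egg RNAs, 0.23 for early zygotic genes and 0.00 for the testis list to 2 decimals. In the maternal egg list, the histone chaperone gene Nasp was 2.41-fold higher. Early zygotic genes lay above their random lists without scaling and with scaling on hybridization controls. The 5 measured strain and sex markers had a median of 0.07. Of the Enhancer of split complex 4 genes were measured, too few for a list, with E(spl)mbeta-HLH at -1.27. In all, 13 of 36 lists stood apart, 6 higher and 7 lower, where lists of genes drawn at random would give 1.8. Genes of 1 list may vary together between any 2 arrays, so the excess over 1.8 does not measure an effect of genotype.

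**Figure D3:**
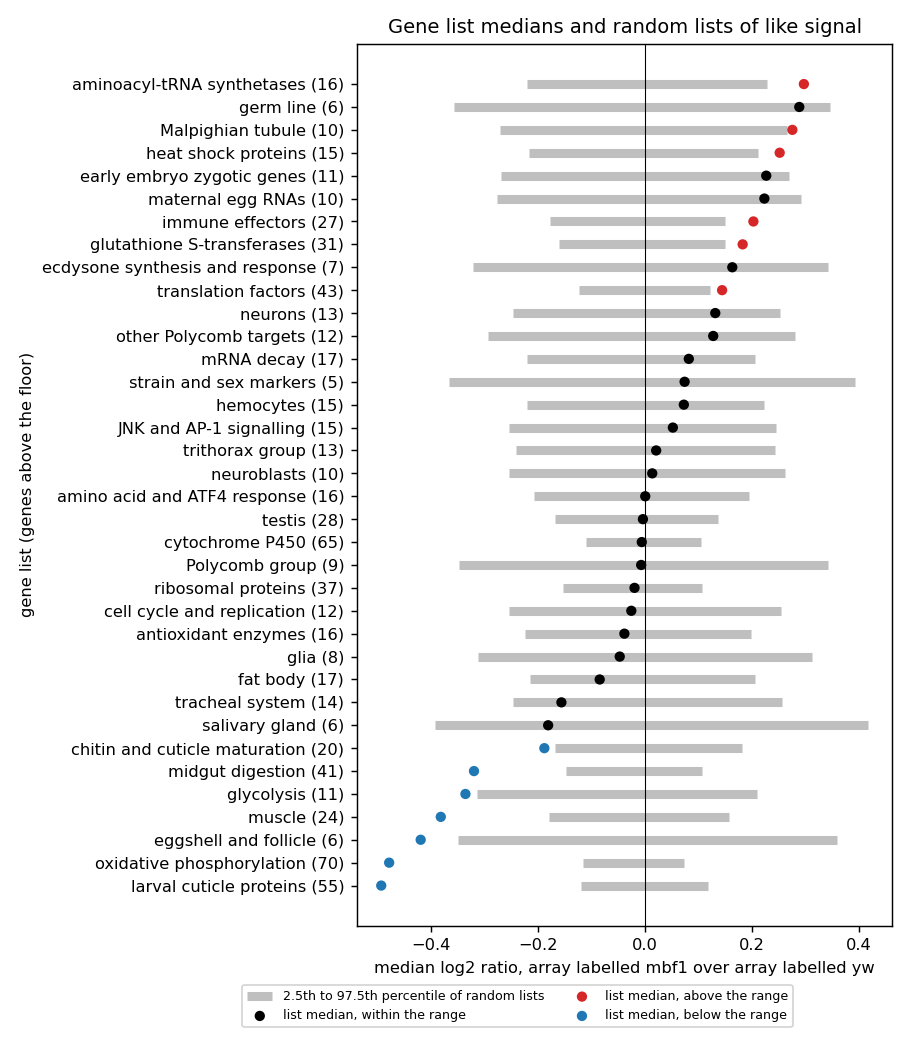
Median log2 ratio of the mbf1 array over the yw array for 36 gene lists (points; red above, blue below, black within the range), with grey bars for the range of 10000 random lists outside which a list was said to stand apart, matched on signal, and the number of measured genes in parentheses. Cuticle and oxidative phosphorylation genes have the lowest medians, -0.49 and -0.48, and aminoacyl-tRNA synthetases the highest, 0.30; without scaling between the arrays the medians of the blue lists other than eggshell were above 0, where the median of all genes was 0.50.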

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

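Probe sets without a single gene symbol stayed outside the comparisons of named genes, and 15 of them were at least 2-fold higher on the mbf1 array than on the control array, in data that no comparison used. That is 1.64% of those above the floor on at least 1 array, close to the 1.51% of measured named genes at least 2-fold higher. Of 1524 such probe sets 913 were above the floor on at least 1 array, and 12 were at least 2-fold lower. A probe set annotated with several genes was at least 17.5-fold lower on the mbf1 array, and one with no gene listed was 3.58-fold higher. Higher as well were 2 probe sets whose several annotated genes include heat shock genes, by 2.53-fold and 2.55-fold.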

How the results depend on the processing

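Scaling on hybridization controls and the P450 list without cyclophilins were chosen after seeing the data, and the other alternatives before the data were examined. The mbf1 ratio of -4.44 stayed negative in all 10 alternatives; it was -3.89 without scaling, by construction of the shift, and -3.74 with a floor at the 60th percentile, which lies above the gene's signal on the mbf1 array. The counts of 116 higher and 124 lower genes depended most on scaling, floor and threshold. They were 797 and 34 without scaling and 235 and 77 with scaling on hybridization controls, which moved the median ratio of all genes to 0.50 and 0.19. With a floor at the 25th percentile they were 279 and 256 and held all 240 genes, with a floor at the 60th percentile 53 and 58, all 111 of them among the 240, and with a pseudocount 226 and 200, with 205 shared. A threshold of 1.5-fold gave 572 and 592 genes, and 3-fold gave 24 and 29, by construction. The other alternatives gave counts within 1.5 times of these, between 83 and 118 higher and between 92 and 121 lower.

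Between 11 and 13 lists stood apart in each alternative, and 8 of the 13 lists did so the same way in each alternative that could measure them. Without scaling the medians turned to 0.073 for oxidative phosphorylation, 0.22 for glycolysis, 0.052 for cuticle proteins, 0.35 for chitin and cuticle maturation, 0.17 for muscle and 0.23 for midgut digestion, since the whole array shifted, and with scaling on hybridization controls chitin and cuticle maturation was at 0.033. Of 348 list medians under alternatives, 264 stayed within the SD of their random lists. Of 61 named genes at least 2-fold apart besides mbf1, 0 changed direction, and 34 stayed at least 2-fold apart in every alternative that measured them. The P450 list without cyclophilins had a median of -0.05 at the 17.5th percentile. The signal over background limits what can be said of 3168 genes under the floor on both arrays.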

Other observations

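All tests in this part were chosen after the result was seen, except those on neighbouring genes and on genes near mbf1; the lists of seminal fluid, phototransduction and yolk proteins were also made only then. Seminal fluid genes were among the brightest on both arrays, and their levels differed little between the genotypes. All 16 were above the floor on both arrays, and 14 were in the top 10% of genes on each. Acp95EF had signals of 3629 and 3115, EbpII 3014 and 2632, EbpIII 2619 and 2211, and SP, the sex peptide, 1765 and 1618. The list's median log2 ratio was -0.03.

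Some adult photoreceptor genes were bright as well. Arr2 and Arr1, the arrestins of the eye, had signals of 1297 and 1186 and of 870.3 and 866.8. On each array 8 of 10 phototransduction genes were above the floor, against 65.9% of all genes on the yw array and 66.2% on the mbf1 array. Galphaq and rdgC were under the floor on both arrays. The genes inaC, at 24.0 and 22.9, and rdgB, at 23.4 and 21.9, lay close to it. The yolk protein gene Yp1 was under the floor on both arrays, and Yp2 and Yp3 had signals of 25.4 and 26.3 and of 31.1 and 36.0. Mst84Da and Mst84Db, genes of the sperm tail chosen after their values were seen, had signals of 2867 and 2462 and of 2572 and 2123.

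Adult male transcripts were thus bright on 2 arrays labelled as embryos, on both alike, so the design offers no group that parts the explanations and no biological explanation was tested. A wrong pairing of probe sets with genes is argued against by the ribosomal proteins, of which 26 of 37, or 70.3%, lay in the top 10% of genes by mean signal. That the values come from adult males stays open as a hypothesis, and no independent test of it was found: the testis list's median mean signal of 225 lay at the 100th percentile of 10000 random lists, whose highest median was 91.9, and for the 29 genes left without alphaTub84D, twe, which the maternal egg list also holds, and the accessory gland genes Mst57Da and Mst57Dc it was 94.3 against 89.7, but this restates the brightness that raised the question and sets signals of different probe sets side by side. Embryo RNA mixed with adult RNA cannot be told apart from it, because 43.1% of 51 Hox, neuroblast and cell cycle genes were above the floor on at least 1 array, against 70.8% of all genes, and no array of embryos alone gives the level to expect. RNA of embryos alone is argued against, for these lists, by their brightness as sets. Of the 29 testis genes just named, from a list fixed before the data were examined, 14 lay in the top 10% by mean signal. Of the 16 seminal fluid genes, a list made later, 14 did so on each array. Adult males and a mixture both stay open, and the genotype comparison might describe adults in whole or in part.

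Respiratory chain genes were lower on the mbf1 array, with a median log2 ratio of -0.48. Scaling that depends on signal is argued against by loess, after which the median was -0.37 and still below all random lists. Control transcripts gave more signal at the 3' end on both arrays. Their 3' over 5' ratios were 3.09 on the yw array and 2.55 on the mbf1 array for eIF-4a, 2.33 and 2.20 for actin, and 2.57 and 2.88 for GAPDH. Between the arrays these ratios differed by a factor of 0.823 for eIF-4a, 0.944 for actin and 1.12 for GAPDH. They thus showed no shift of RNA integrity in a common direction. These few controls cannot exclude an effect as small as the list's median. A smaller share of muscle RNA stays undecided: loss of muscle alone should leave respiratory genes higher than muscle genes, but the 53 without copies whose symbols end in L or in L and a digit had a median of -0.54 and muscle genes, some of them not particular to muscle, one of -0.38, and the difference from unrounded values was -0.15, with a 95% bootstrap interval over genes of -0.42 to 0.10. The 17 copies ending in L had a median of -0.020, but they are known mostly as testis-biased and were dimmer, with a median yw signal of 79.7 against 1220, so they do not tell muscle from other tissues outside the testis. An effect of the mbf1 mutation itself stays open and was not tested, since the genotype and the array are the same split.

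The 240 genes that differed at least 2-fold may in part reflect strain background. Adjacent measured genes at least 2-fold apart in the same direction formed 12 pairs, where random gene orders gave a median of 4 and exceeded 8 in at most 2.5% of orders, with a highest count of 13; the pairs include Cyp6a23 with Cyp6a9, GstD10 with GstD9 and Acp1 with CG7214, so shared regulation or shared sequence within gene families stays open too. Background carried along with mbf1 stays open. Of the 100 measured genes nearest mbf1, 2 differed at least 2-fold, against a median of 3 in other blocks of its chromosome arm. These small counts showed no local excess. A linked segment longer than the block would reach the other blocks too, so the comparison cannot decide. Noise of single probe sets stays open. Of 14 other probe sets above the floor, of 13 such genes, 11 had a ratio of the same sign as the gene's main probe set. Only 4 had a yw signal that left room for a 2-fold difference in that direction above the floor, and 1 of them, or 25%, showed it. With the higher genes whose other probe set started under the floor it was 1 of 6, or 16.7%, and both counts are too small to decide. Which of the 240 differences come from the mutation was not tested.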
